A study of Homo sapiens with 6 samples.

How the data were processed

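Total RNA of HCC1937/BRCA1 and HCC1937 cells was profiled on 6 single-colour Exiqon LNA arrays, 3 technical replicates per line, per the labels, which do not say whether these share an RNA preparation. Each array had its own slide. Scan days paired the lines, with 1 array of each line on each of 3 days, and the replicate number of the labels followed the scan day. The deposited scanner files give spot signals as linear intensity, made with Agilent Feature Extraction 9.5.3.1 per the file headers, with 1 background value subtracted per array and no normalization between arrays. The deposited value table gives log2 values, 1 per probe, whose columns share nearly 1 distribution; limma is named in the labels and the method is not stated. Its columns correlated at 0.985 to 0.999 with normexp background correction and quantile normalization rebuilt from the scanner files, across probes. It served only as an alternative.

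The arrays carry 1978 probes in common with 4 spots each, and 13 probes are in only 1 of the 2 layouts used. Of these, 1264 name human miRNAs, including 435 miRPlus probes of the maker and 5 probes with several human names. Spots with a scanner flag for poor quality were dropped and the signal of a probe was the mean over the rest. The background threshold of an array was the mean plus 2.6 SD of its spots of 7 negative-control probes, and a probe was above background where over 50% of its spots exceeded it. The scanner's own flag for signal above background was first planned for this but passed most negative-control spots, so the definition was changed before any comparison of the lines was made and the flag became an alternative. Thresholds ranged from 12.3 to 65.9 and the share of human probes above background from 14.9% to 47.2%. The number of arrays limits the precision.

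Each array was scaled to the 75th percentile over the 176 human probes above background on all 6 arrays. The factors ranged from 0.280 to 8.44, the largest for replicate 2 of HCC1937/BRCA1. Scaled signals under 24.5 (4.62 on the log2 scale, the median scaled threshold) were set to that floor, and log2 was taken. Human miRNAs above background on every array of at least 1 line were tested, 244 in all and 91 of them miRPlus. miR-146a failed this filter because of replicate 2 of HCC1937/BRCA1 and was added to the fit to give its estimate. limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided, Benjamini-Hochberg at 0.05) compared HCC1937/BRCA1 with HCC1937. A fold given as at least N compares a signal above background with the highest of the other array's signal, its threshold and the floor, all scaled. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

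The fit had no block, because the labels state no pairing. Pairing was checked by correlating, across miRNAs, the deviations of the arrays of each replicate number from their line's mean, which gave 0.637, 0.453 and 0.614. The fit with a replicate block is therefore given beside it for counts, lists and the miRNAs of the title. Values of other single miRNAs come from the fit without a block unless stated. Lists of miRNAs were written before the data were examined, 28 in all, and the 13 with at least 3 tested members were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, all in limma. Of the others, 11 had fewer tested members and 4 had none.

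miRNAs were named by a rule set before the data were examined: those of the title, the 10 largest changes in each direction among miRNAs that passed without overlap of the lines, the strongest called members of each list and its brightest member that did not pass, and the 5 brightest human probes. Other miRNAs named were chosen after their values were seen. BRCA1 mRNA has no probe on these arrays. Probes of other organisms, small nuclear RNAs and 157 probes without a name were kept apart.

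Alternatives set in advance were normexp background correction, a percentile over all human probes, quantile, median and spike-in scaling, no filter or a stricter filter on dim probes, a lower floor, medians over spots, an intensity trend, a replicate block, the value table, and leaving out each array. Alternatives chosen after seeing the data were the scanner's background flag, a background from murine virus probes, leaving out both replicate 2 arrays with and without a block, quantile normalization with a block, and leaving out replicate 2 of HCC1937/BRCA1 with quantile normalization. The procedure was tested on simulated data of 244 miRNAs in 20 simulations, where it recovered few planted 2-fold differences, most of 8-fold, and made no false calls. With a block it recovered more and made some false calls.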

Results

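MicroRNAs (miRNAs, short RNAs that lower the output of their target mRNAs) were measured in a pair of isogenic human breast cancer cell lines. HCC1937 is a breast cancer line, and HCC1937/BRCA1 is its counterpart that expresses BRCA1, a protein of homologous recombination repair. BRCA1 itself was not measured on these arrays. Total RNA of each line was labelled with the dye Hy3 and hybridised to Exiqon LNA miRNA arrays, with 3 technical replicates per line and 6 arrays in all. The depth of an array is its signal over background, which differed widely. In HCC1937/BRCA1, 592, 188 and 596 of the 1264 human miRNA probes were above background on replicates 1, 2 and 3. In HCC1937 the counts were 563, 240 and 437. Replicate 2 of HCC1937/BRCA1 was the dimmest array, with a 75th percentile signal of 61.8 against 380 to 1863 on the other arrays. Correlations of log2 signal between arrays, taken across 244 miRNAs that are not independent replicates, ranged from 0.880 to 0.972.

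The only comparison was HCC1937/BRCA1 against HCC1937, and it asked which miRNAs differ with BRCA1 expression. miR-146a, which NF-kB induces and which represses the signalling adaptors TRAF6 and IRAK1, was above background on replicates 1 and 3 of HCC1937/BRCA1 and on no HCC1937 array. miR-205, an epithelial miRNA that represses the ZEB transcription factors, averaged 2.31-fold higher in HCC1937/BRCA1, and the 3 arrays of each line did not overlap. The 8 tested members of the miR-17-92 cluster, an oncogenic polycistron activated by MYC, and of its relative on the X chromosome had lower means in HCC1937/BRCA1, although 0 passed over all miRNAs in limma and their list had an adjusted p of 0.408 with an estimated correlation. miR-19a was at 6.82 ± 0.25 against 8.30 ± 0.18 (log2, SD, n = 3 per line) and miR-20a at 6.85 ± 0.09 against 8.13 ± 0.54. miR-99b, which lies beside let-7e and miR-125a, averaged 0.59 higher on the log2 scale, with overlapping arrays.

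Of 244 human miRNAs tested with limma on all 6 arrays, 0 passed an adjusted p of 0.05, with a lowest adjusted p of 0.287. At an unadjusted p under 0.05 there were 26, of which 5 were higher and 21 lower in HCC1937/BRCA1, where 12.2 were the number chance gives. The direction of that count depended on the processing: it was 5 higher and 0 lower with spike-in scaling, 12 and 8 in the authors' value table and 8 and 8 of 160 miRNAs tested with a murine virus background, and over 24 alternatives lower ones were more in 17, fewer in 5 and as many in 2. With the replicate number as a block in limma, 0 passed and 52 had an unadjusted p under 0.05. The arrays of the lines did not overlap for 47 miRNAs (19.3%), of which 7 were higher and 40 lower in HCC1937/BRCA1. Chance gives 10% where the pairing of arrays by scan day is ignored. The median difference over the 244 miRNAs was -0.21 (log2), so differences are also given relative to it. Leaving out replicate 2 of HCC1937/BRCA1 changed the count: 6 of 523 miRNAs then passed. All p-values measure only the spread between technical replicates, not between cultures.

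Among the miRNAs of the study's title, miR-146a had a signal of 522 on replicate 1 and 1048 on replicate 3 of HCC1937/BRCA1, 18.6 and 36.8 times the background threshold of those arrays. On replicate 2 its signal was 5.83, 0.476 times the threshold. The 3 HCC1937 arrays gave 21.7, 37.2 and 32.8, all under their thresholds. On the arrays scanned on the first day, miR-146a was at least 10.7-fold higher in HCC1937/BRCA1, and on those of the last day at least 12.0-fold higher. Neither array of the day of replicate 2 was above background, so that day gives no fold. Over all arrays, with the signal of replicate 2 taken as it was, the ratio to the same limits was 4.8. The means were 7.39 ± 1.54 in HCC1937/BRCA1 and 4.84 ± 0.20 in HCC1937 (log2, SD, n = 3), a difference of 2.55 (SE 0.71) with an adjusted p of 0.259 in limma. The log2 difference rests on signals of 4 arrays that were not above background, 1 of them set to the floor, and is not a bound.

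miR-205 reached 11.32 ± 0.81 in HCC1937/BRCA1 and 10.12 ± 0.24 in HCC1937 (log2, SD, n = 3). The difference of 1.21 (SE 0.45, 95% interval 0.16 to 2.26) had an adjusted p of 0.406 in limma and was positive on 3 of 3 scan days, at 1.55, 0.54 and 1.53. miR-99b reached 7.96 ± 0.77 and 7.37 ± 0.26. Its difference of 0.59 (SE 0.44, 95% interval -0.44 to 1.62) had an adjusted p of 0.702 in limma, with 0.96 and 1.28 on the first and last days and -0.47 on the day of replicate 2. Relative to the median of all tested miRNAs, the differences were 1.42 for miR-205 and 0.80 for miR-99b. In limma with the replicate block, the adjusted p was 0.134 for miR-146a (SE 0.64), 0.132 for miR-205 (SE 0.29) and 0.487 for miR-99b (SE 0.39). Without replicate 2 of HCC1937/BRCA1, the differences were 3.66 (SE 0.37) for miR-146a, 1.75 (SE 0.36) for miR-205 and 1.12 for miR-99b, with adjusted p of 2.5e-05, 0.0204 and 0.168 in limma. Over all alternatives the adjusted p ranged from 2.4e-05 to 1.0 for miR-146a, from 0.00116 to 1.0 for miR-205 and from 0.00443 to 1.0 for miR-99b.

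**Figure D1:**
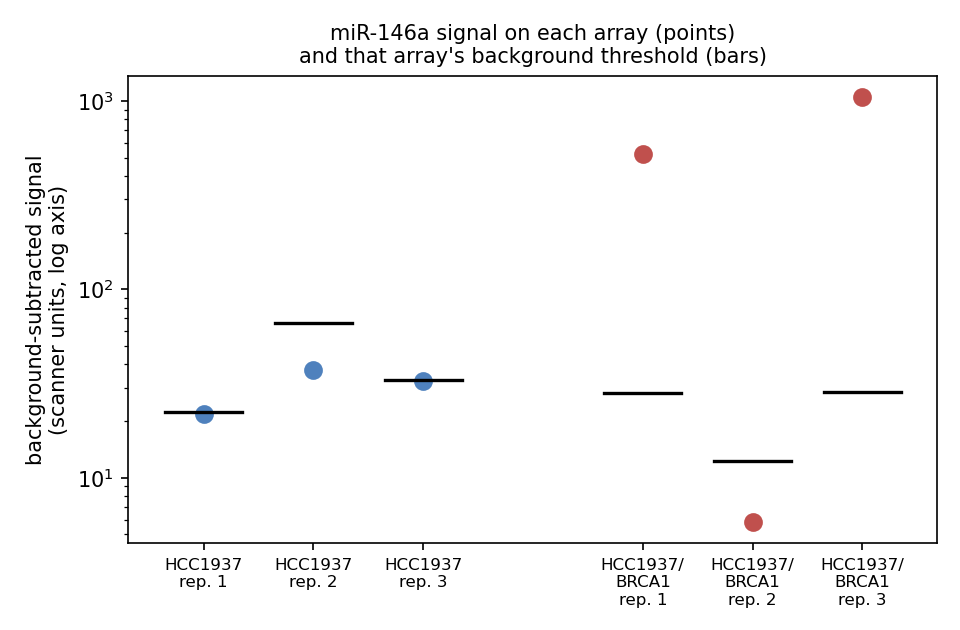
Background-subtracted signal of miR-146a (scanner units, log axis) on each of the 6 arrays (points), with that array's background threshold (bars). Replicates 1 and 3 of HCC1937/BRCA1, at 522 and 1048, lie above their thresholds and the other 4 arrays lie below theirs.

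The list of the miR-17-92 cluster and its paralogs had the relative median farthest from 0 of the lists tested. Of 13 members, 11 were tested, and their median difference was -0.95, or -0.74 relative to all tested miRNAs. Relative medians were -0.46, -0.84 and -0.82 on the 3 scan days. Over all 244 miRNAs 0 members passed in limma, and 7 had an unadjusted p under 0.05. Adjusted over the list alone, 7 passed, all lower in HCC1937/BRCA1: miR-19a at -1.48 (SE 0.31), miR-20a at -1.28 (SE 0.37), miR-19b at -1.17 (SE 0.31), miR-18a at -1.08 (SE 0.31), miR-106a at -1.03 (SE 0.32), miR-18b at -0.95 (SE 0.35) and miR-17 at -0.93 (SE 0.33). The other tested members were miR-20b at -0.77, miR-106b at -0.29, miR-25 at -0.02 and miR-93 at 0.11. The list passed camera in limma with an adjusted p of 2.8e-04, and its adjusted p with an estimated correlation was 0.408. In fry, which asks whether members move one way on balance and makes no comparison with other miRNAs, the list had an adjusted p of 0.0126 in limma, and of 0.0638 with the replicate block, where it did not pass. The fry call held with a lower floor (adjusted p 0.0122) but not with quantile normalization (0.351), median scaling (0.450) or the authors' table (0.808). With spike-in scaling the direction in fry was upward (adjusted p 0.998). Without replicate 2 of HCC1937/BRCA1, the relative shift was -0.37 and the adjusted p of camera in limma was 0.0839. Its range over all alternatives was 1.1e-18 to 0.408, where 0.408 is camera with an estimated correlation on the main values. With an estimated correlation, some alternatives gave a higher adjusted p in camera, such as 0.930 with the scanner's flag.

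In the RefSeq annotation of GRCh38.p14, the 6 genes from MIR17 to MIR92A1 are neighbours, as are the 3 genes MIR106B, MIR93 and MIR25. The 4 genes counted for the MIR106A cluster lie in a span of 6 genes, and the genes between them were not counted. A miRNA encoded in both the MIR17 and MIR106A clusters would be counted for the MIR17 cluster alone. The averages therefore do not fully separate these clusters. Relative to all tested miRNAs, the 5 tested members of the MIR17 cluster averaged -0.95 (SE 0.07 over 3 scan days). The 3 tested members of the MIR106A cluster on the X chromosome averaged -0.68 (SE 0.10). They share seed families with members of the MIR17 cluster, and cross-hybridisation was not checked by probe sequence, so they are not separate evidence. The MIR106B cluster averaged 0.17 (SE 0.31). Without replicate 2 of HCC1937/BRCA1, the MIR17, MIR106A and MIR106B clusters averaged -0.54, -0.26 and 0.51, over 6, 4 and 3 tested members. Under 24 alternatives the MIR17 and MIR106A clusters were below the median in all 24. The MIR106B cluster was above it in 22 and below it in 2, with no filter on dim probes and without replicate 3 of HCC1937/BRCA1. The MIR17 cluster lay below the MIR106B cluster by a mean of -1.12 ± 0.43 (log2, SD, n = 3 scan days), negative on 3 of 3 days, with a two-sided exact sign-flip p of 0.25, the smallest that 3 days can give. The contrast was chosen after its values were seen, and so few days leave this test unable to decide. On the day of replicate 2 the MIR106B cluster was also below the median, at -0.45. In the MIR17 and MIR106A clusters miR-92a and miR-363 were not tested, and miR-363 was above background only on replicates 1 and 3 of HCC1937/BRCA1, at 1.20 and 1.54 times the threshold.

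**Figure D2:**
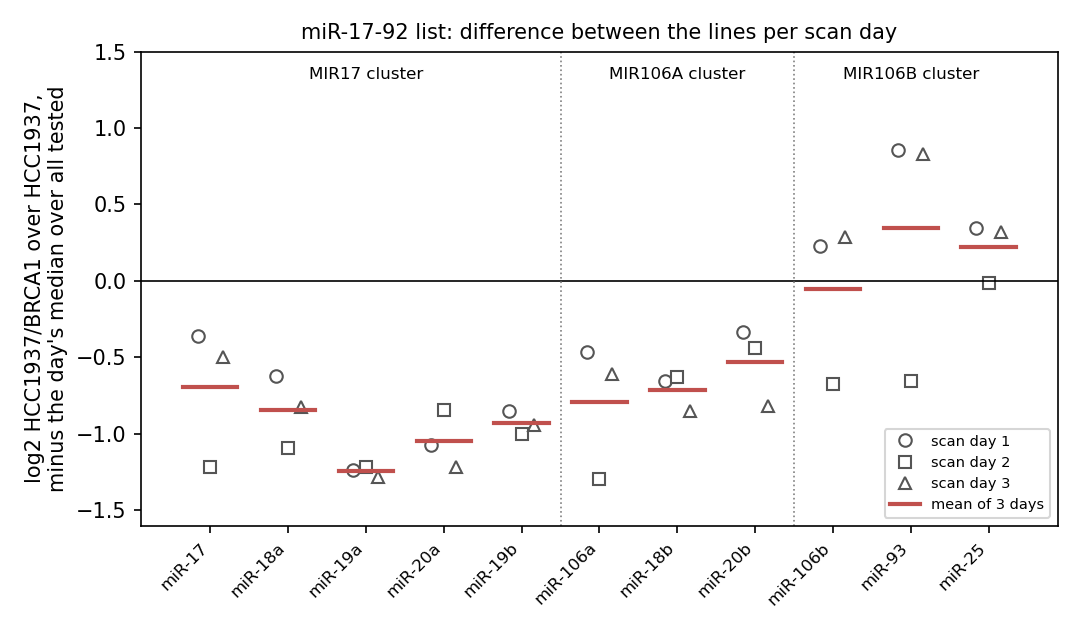
Difference of each tested miR-17-92 list member between HCC1937/BRCA1 and HCC1937 minus that day's median over all tested miRNAs (log2, vertical axis), on each of the 3 scan days (open symbols) with the mean of the days (bars), grouped by genomic cluster. The MIR17 and MIR106A clusters average -0.95 and -0.68, and the MIR106B cluster averages 0.17, with a sign that changed in 2 of 24 alternatives. Without replicate 2 of HCC1937/BRCA1 these clusters average -0.54, -0.26 and 0.51 (not drawn).

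Of the 28 miRNA lists fixed before the data were examined, 13 had at least 3 tested members, and the miR-17-92 list was the 1 that passed camera. With an estimated correlation 0 of the 13 passed in limma (1 at an unadjusted p under 0.05), and 2 passed fry without the replicate block and 0 with it. The mammary basal-type list had a relative median of 0.36 with an adjusted p of 0.2 in camera of limma, and its relative medians were 0.89 and 0.94 on the first and last days and -0.10 on the day of replicate 2. The miR-200 family, which represses ZEB factors together with miR-205, had a relative median of 0.39 (adjusted p 0.399 in camera of limma), and its brightest member miR-200c differed by 0.18 (SE 0.35). Its members went both ways, with miR-141 at -0.86 (SE 0.54; -1.59, 0.75 and -1.75 on the 3 days), and the mean difference of the family was -0.07 where its median was 0.18. The miR-23/27/24 clusters had a relative median of 0.38 (adjusted p 0.245 in camera of limma), with miR-24 at 0.22 (SE 0.33). The list of the miR-99, miR-125 and let-7e clusters and that of NF-kB-linked miRNAs had relative medians of 0.32 and 0.31, with let-7c and miR-21 as their brightest members, while their mean differences (-0.05 and -0.01) and median differences (0.11 and 0.10) before that adjustment differed in sign. Both were positive on the first and last days (0.91 and 0.88, 0.89 and 0.90) and negative on the day of replicate 2 (-0.64 and -0.66). Only 4 of the 8 NF-kB-linked miRNAs were tested. The filter left out miR-146a, miR-146b-5p, miR-155 and miR-9, which were not above background on every array of a line.

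The let-7 family, which represses RAS and HMGA2, had a relative median of 0.09, and its 9 members included let-7f at -0.28 (SE 0.33) and let-7c at -0.06 (SE 0.34). The miR-15/16 family, known for repressing BCL2, had a relative median of -0.23 (adjusted p 0.263 in camera of limma), with miR-16 at -0.49 (SE 0.29). The miR-30 family had a relative median of -0.14 and an adjusted p of 0.778 in camera. It passed fry in limma with an adjusted p of 0.00213, downward on balance, but not with the replicate block (0.0638), and miR-30a was at -0.43 (SE 0.30). The fry call of this family held with a lower floor (adjusted p 0.00233) but not with quantile normalization (0.939) or median scaling (0.889). Its direction in fry turned upward with spike-in scaling (adjusted p 0.704), the authors' table (0.852) and the murine virus background (0.927). The metastasis-promoting list, with the oncogenic miR-21 at -0.44 (SE 0.35), had a relative median of -0.23. The metastasis-restraining and luminal-type lists, in both of which miR-200c was the brightest member, had relative medians of 0.09 and 0.07. The hypoxia-linked list had a relative median of -0.04, with miR-26b at -0.60 (SE 0.35). The raw differences of let-7c, let-7f, miR-16, miR-21, miR-26b and miR-30a changed sign under some of the 24 alternatives, while those of miR-17, miR-24 and miR-200c kept theirs.

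**Figure D3:**
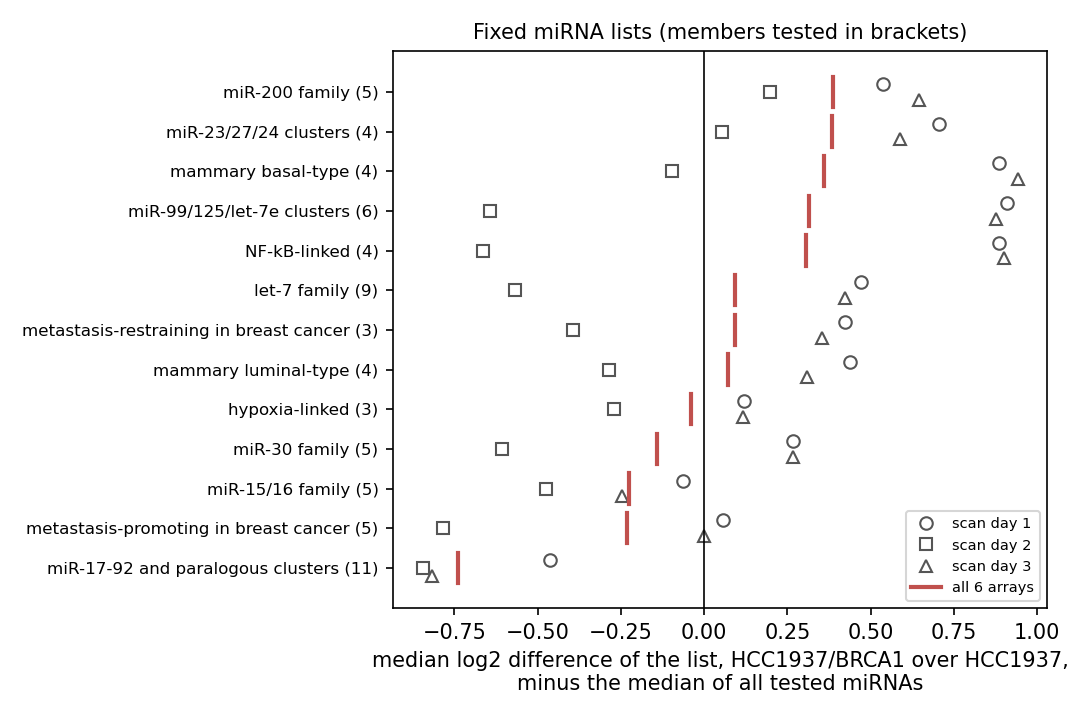
Median log2 difference of each tested list between HCC1937/BRCA1 and HCC1937 minus the median of all tested miRNAs (horizontal axis), on each of the 3 scan days (open symbols) and over all 6 arrays (bars). The miR-17-92 list lies at -0.46, -0.84 and -0.82 on the 3 days, while the mammary basal-type list lies at 0.89, -0.10 and 0.94.

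Outside these lists, the 5 brightest human probes were miRPlus-E1246 at -0.99 (SE 0.41), miRPlus-E1078 at -0.64 (SE 0.50), miRPlus-E1218 at -0.62 (SE 0.40), miR-1826 at -0.55 (SE 0.33) and miRPlus-E1170 at -1.07 (SE 0.46). Those of miRPlus-E1078, miRPlus-E1218 and miR-1826 changed sign under some alternatives. miRPlus names are the maker's own candidate miRNAs. Several miRNAs with non-overlapping arrays were named after their values were seen: miR-181a, a regulator of lymphocyte signalling, at 1.22 (SE 0.35), miR-193a-3p at -0.99 (SE 0.32), miR-424 at -1.02 (SE 0.36) and miR-100, a repressor of mTOR and a family member of miR-99b, at -1.43 (SE 0.51). These estimates kept their sign under all alternatives that gave them.

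Without replicate 2 of HCC1937/BRCA1, 4 miRNAs rose and 2 fell in limma, on 2 arrays against 3. The 4 higher ones were miR-146a, miR-205, miR-146b-5p, which shares its seed with miR-146a, at 2.85 (SE 0.36), and miRPlus-F1216 at 2.83 (SE 0.38). The 2 lower ones were miR-29b, a repressor of collagens and DNA methyltransferases, at -1.92 (SE 0.37), and miR-100 at -1.77 (SE 0.41). At an unadjusted p under 0.05 there were 101, of which 11 were higher and 90 lower, with a median difference of -0.56 over the 523 miRNAs. With quantile normalization on the same arrays 67 were higher and 25 lower, and with both replicate 2 arrays left out, on 4 arrays, 29 were higher and 29 lower. Without replicate 2 of HCC1937/BRCA1 alone, 9 lists passed camera, the title's own among them, all upward relative to the others, and 0 passed with an estimated correlation (5 at an unadjusted p under 0.05, lowest adjusted p 0.0916 in limma). The title's list was chosen by the study on these samples and is not independent evidence. Nor are lists that share its members: the NF-kB-linked, BRCA1-targeting and metastasis-restraining lists hold miR-146a and miR-146b-5p, the mammary basal-type list holds miR-205 and the list of the miR-99 clusters holds miR-99b.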

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

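The tests of single scan days, of the miR-19 pair, of exchanged labels, of differences in small nuclear RNAs and of the miR-17-92 list on the day of replicate 2 were chosen only after the result was seen, and the others were written before.

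Signal above background on all 6 arrays, at the thresholds used for the human miRNAs, was also found in probes outside the human set, which the comparison does not use. Among 350 probes with only rodent names, 39 were above background (11.1%), where many rodent miRNAs have human relatives of near-identical sequence. Among 18 probes of small nuclear and nucleolar RNAs there were 13 (72.2%). At the scaling used, all 16 of these probes above background on every array of a line had lower estimates in HCC1937/BRCA1. Of them 7 were without overlap (43.8%, against 16.4% of miRNAs), where chance gives 10% over both directions with the pairing ignored. Their median relative to the miRNAs was -0.34, with -0.14, -0.58 and -0.26 on the 3 days. Over 21 alternatives the relative median was below 0 in 20 and at 0.02 without replicate 2 of HCC1937/BRCA1, and the raw median of -0.55 turned to 0.30 with spike-in scaling. Among 157 probes without a name in the files there were 57 (36.3%). Probes of human viruses gave 4 of 78 and those of murine viruses 2 of 39, the same share of 5.13%. A ribosomal RNA probe gave the other 1.

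The tested miR-17-92 list members had a relative median of -0.74 in HCC1937/BRCA1, and small nuclear and nucleolar RNA probes were shifted the same way at -0.34. Scaling that depends on intensity is argued against by random lists of like level, as the list's median lay at percentile 0.01 of 10000 draws, the smallest they can give. Over the 7 members above background on all arrays it lay at 0.03, and at 0.67, 2.57 and 3.73 on the 3 single days. The draws do not allow for correlation between members of a list, so these percentiles are not p-values. The dim replicate 2 array of HCC1937/BRCA1 as the cause is argued against by the other days, since the higher of their relative medians was -0.46, although the call ends without that array (relative shift -0.37 over 523 miRNAs). Cross-hybridisation among near-identical miR-17 family probes is argued against as the whole cause, since the miR-19 pair, of another seed family, averaged -1.09 (SE 0.02). That pair is not among the tested members counted for the MIR106A cluster, where cross-hybridisation stays open. A difference that goes with BRCA1 expression stays open and was not tested, as do one between RNA preparations of the lines and one shared with other small RNAs, and miR-363 of the same list was above background only on replicates 1 and 3 of HCC1937/BRCA1, at 1.20 and 1.54 times the threshold.

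miR-146a was at background on replicate 2 of HCC1937/BRCA1 and far above it on replicates 1 and 3. Low brightness of that array is argued against by 36 of 37 miRNAs of like level on the other HCC1937/BRCA1 arrays being above background on it (97.3%, exact 95% interval 85.8 to 99.9). The 1 that was not is miR-146b-5p, which shares its seed with miR-146a. Exchanged labels of the replicate 2 arrays are argued against by miR-146a lying at 0.564 times the threshold on the array labelled HCC1937. RNA of the HCC1937 line on the array labelled HCC1937/BRCA1 replicate 2 could give this: of 15 miRNAs over 2-fold from the day's median difference in 1 direction on both other days, 6 lay in that direction from the median of this day (40.0%, exact 95% interval 16.3 to 67.7), and their median size in that direction was -0.07 against 1.27 on the other days. The miR-17-92 list goes partly against it, as arrays of the same RNA would leave it near other miRNAs of like level. On this day its median difference was -0.62 over all 11 tested members, against 0.12 for random lists of like level. Over the 7 above background on all arrays it was -0.78 against -0.20. The day's median over all tested miRNAs was 0.22, so miRNAs of like level lay below it too. Relative to the median of this day, the MIR17 cluster was at -1.08, the MIR106A cluster at -0.79 and the miR-19 pair at -1.11. The MIR17 cluster was at -0.83 and -0.95 on the first and last days. The list's median on this day lay at percentile 0.21 of random lists over all 11 tested members. Over the 7 above background on all arrays it lay at 2.57, against 0.67 on the first day and 3.73 on the last. The value over these 7 therefore does not set this day apart. The 15 miRNAs above go the other way, but they include miR-19a and miR-20a of the list, which kept their direction. They were chosen by their size on the other days, so a smaller size on this day could follow from that choice. A difference of array brightness could give it too, and the question stays undecided. A lower miR-146a level in the RNA of that array stays open only if the technical replicates do not share 1 RNA preparation, which the labels do not say, and was not tested.

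Day differences between the lines correlated across miRNAs at 0.86 between the first and last days, as a difference between the lines could also give. With the day of replicate 2 they correlated at 0.06 and 0.14, which the lines alone do not explain. The HCC1937/BRCA1 array had the higher median ratio of signal to threshold on the first and last days (9.16 against 6.62, 16.3 against 9.10). On the day of replicate 2 it had the lower one (2.02 against 3.64). These values do not separate a difference between the lines from one of array brightness. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. At an unadjusted p under 0.05, the real split gave 26 and the highest other 94, and 2 of 10 gave as many. Past the threshold, the real split gave 0 and the highest other 55, so 10 of 10 gave as many, and for lists it gave 1 with a highest other of 4, so 8 of 10 gave as many. The split that called 55 set replicates 1 and 3 of HCC1937/BRCA1 and replicate 3 of HCC1937 against the rest. These 3 have the highest ratios of signal to threshold, which points to a structure of the samples that could follow array brightness. Both replicate 3 arrays also share a scan day and are the only arrays of their probe layout. Brightness, layout and scan day cannot be told apart here. Of the 4 splits that part all 3 pairs, the real one gave 26 at an unadjusted p under 0.05. The other ones gave 0, 7 and 0. With the replicate block the real split gave 52.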

How the results depend on the processing

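Alternatives that leave out both replicate 2 arrays, quantile normalization with a block, replicate 2 of HCC1937/BRCA1 left out with quantile normalization, the scanner's flag and the murine virus background were chosen only after the result was seen. Signal over background limits the tests: the median ratio of signal to threshold was 2.02 on replicate 2 of HCC1937/BRCA1 and 3.64 to 16.3 on the others. Slide or scan as a block was not run separately, since each slide held 1 array and the scan day is the replicate number. With the replicate block the count past the threshold stayed 0, 1 list passed camera and 0 passed fry. The main fit called 0 miRNAs, and the camera call of the miR-17-92 list did not reverse. The fry calls of that list and of the miR-30 family turned upward under some alternatives. With spike-in scaling their adjusted p in fry was 0.998 and 0.704. Of 24 alternatives, 20 kept 0 miRNAs past the threshold in limma (3 to 194 at an unadjusted p under 0.05). Scaling moved the median difference from -0.21 to 0.45 with spike-in probes and -0.06 with quantile normalization.

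With an estimated correlation 0 lists passed in the 23 of 24 alternatives that gave one (lowest adjusted p 0.0916 in limma), so the list counts that follow rest on the preset correlation (both replicate 2 arrays left out with a block gave no estimate). With both replicate 2 arrays left out, 10 miRNAs passed (9 higher, 1 lower) and 8 lists (0 with an estimated correlation, lowest adjusted p 0.426 in limma), and the differences were 4.13 for miR-146a, 1.53 for miR-99b and 1.95 for miR-205. With a block added, 100 passed (43 higher, 57 lower) and 7 lists, with the same 4.13, 1.53 and 1.95, from a fit with 1 residual degree of freedom per miRNA; on simulated data of 6 arrays a block gave 1.35 false calls per simulation. With replicate 2 of HCC1937/BRCA1 left out and quantile normalization, 13 passed (12 higher, 1 lower) and 5 lists (0 with an estimated correlation, lowest adjusted p 0.415 in limma), with 4.10, 1.25 and 2.48. Without 1 array at a time, 0 to 6 passed (0 to 4 higher, 0 to 2 lower), the 6 without replicate 2 of HCC1937/BRCA1, and 1 to 9 lists, and the ranges were 1.95 to 3.66 for miR-146a, 0.34 to 1.12 for miR-99b and 0.92 to 1.75 for miR-205. Of those 6 miRNAs, 5, 6 and 4 were among the 10, 100 and 13. Leaving out the dim array also raised the number tested, and the cause was not tested further.

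Lists past camera numbered 0 with normexp, 0 with the percentile over all human probes, 2 with quantile normalization, 4 with no filter, 2 with the authors' table, 2 with the scanner's flag, 2 with quantile normalization and a block, 0 with an estimated correlation, and 2 with fry. The relative shift of the miR-17-92 list stayed below 0 under all 26 alternatives and missed the threshold with normexp (-0.38), the percentile over all human probes (-0.63), both replicate 2 arrays left out (-0.44, and -0.44 with a block), replicate 2 of HCC1937/BRCA1 left out with quantile normalization (-0.65) and an estimated correlation (-0.74). Without 1 array at a time it ranged from -1.09 to -0.37, and the -0.37, without replicate 2 of HCC1937/BRCA1, missed it too. The cause was not tested.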

Other observations

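No test in this part was planned, and all were chosen after the values were seen.

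Among human probes, 42 (14 of them miRPlus) were above background on replicates 1 and 3 of HCC1937/BRCA1 and on no HCC1937 array, and 2 showed the reverse. None of the 42 (0) was above background on replicate 2 of HCC1937/BRCA1. miR-146a led them at 18.6 and 36.8 times the threshold, and the next, miRPlus-E1072, reached 3.68 and 3.65. miR-215, miR-192, miR-194 and miR-34c-5p, which are p53-responsive, were among them, 4 of the 9 miRNAs of that list, at 1.93 and 2.26 times the threshold for miR-215, 1.10 and 1.47 for miR-192, 1.11 and 1.34 for miR-34c-5p and 1.10 and 1.87 for miR-194. The mean signal of miR-194 reached 1.39 times the threshold on an HCC1937 array where not over 50% of its spots exceeded it. The tested members of that list, miR-107 at -0.51 (SE 0.32) and miR-34b at -0.09 (SE 0.40), had lower means in HCC1937/BRCA1. These signals lie near background, and the arrays of HCC1937/BRCA1 on those days had more human probes above it (592 and 596) than those of HCC1937 (563 and 437).

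miR-99b and miR-100 belong to the same seed family and lie in different clusters. The difference of miR-99b between the lines exceeded that of miR-100 by 2.02 ± 0.99 (log2, SD, n = 3 scan days), with 2.56, 0.87 and 2.61 on the 3 days and a two-sided exact sign-flip p of 0.25, the smallest that 3 days can give. It was above 0 in 23 of 23 alternatives, from 1.42 to 2.89. miR-100 was above background on 2 of 3 HCC1937/BRCA1 arrays, at 4.75 and 4.72 on replicates 1 and 3 where the floor was 4.62, and so few days leave the test unable to decide.

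Mouse and rat probes for miR-17 family members, outside the comparison, gave differences of -1.12 for mmu-miR-20a, -1.10 for mmu-miR-17 and -0.44 for mmu-miR-106a. Each was without overlap of the lines, as 3 arrays against 3 give by chance in 10% of cases with the pairing ignored. These rodent probes detect sequences near those of the human probes and are not independent of them.

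Markers of other cell types (blood, stroma and endothelium, muscle, nerve, liver and serum), 5 lists with 35 members on the arrays, had 2 members above background on all 6 arrays, miR-129-5p at -0.23 and miR-885-5p at -0.13. Above background on none were 13, and the highest member, miR-208a, reached 3.96 times the threshold.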
